A study of Mus musculus with 8 samples.

How the data were processed

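RNA from sorted mouse pro-B cells was measured on 8 Agilent arrays of 1 colour (Cy3), 2 for each of 4 groups, numbered 1 and 2 in the labels as separate sorts. Per the labels, the cells came from BALB/c mice that lack Rag1, the recombinase gene whose loss holds B cells at the pro-B stage. Bone marrow (BM) cells of 2 mice, or fetal liver (FL) cells of embryos at gestation day 16 (on average 8 per sort), were sorted onto OP9 stromal cells with IL-7 in a plate of 24 wells. A day later 12 wells received the retrovirus under test and 12 its empty vector. BM cells received Lin28b in the pMIG vector, FL cells let-7b in an MSCV vector. Cells positive for the vector's GFP were sorted 4 days after transduction, and 100 ng of total RNA was amplified and labelled.

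The scanner files hold spot intensities, which Agilent Feature Extraction 9.5.3.1 corrected for background before they were deposited, per the file headers. The authors also deposited 1 table of normalized log2 values, whose normalization is not given in the sources used here. Set against the scanner signals, its columns rose with a slope of 0.957 to 1.01 on bright spots, so its scale was taken as log2. Its column medians were 7.22 on all BM arrays and 6.16 on all FL arrays, so the tissues were taken as normalized separately, and the table was tested within a tissue only. Its centring is unknown. Probe positions are those of the array design (mouse build mm9, per the file headers).

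An array held 44397 spots, of which 1377 control spots were left out. The value used was log2 of the processed signal minus the array's 75th percentile of it over the other 43020 spots, and every level below is log2 relative to that percentile. Copies of a probe were averaged (399 probes were printed 10 times), and 31 probes with an outlier spot on at least 1 array were left out. Of 39429 probes, 10989 were well above background on fewer than 2 of the 8 arrays and were left out, which kept 28409. For each gene the probe of highest mean over the 8 arrays was tested, which gave 22927 genes or unnamed transcripts. Kept probes were named by matching accessions (19856), symbols (1960) or synonyms (563) to a RefSeq gene table of assembly GRCm38.p6, from which no coordinate was used. The other 6030 kept the name in the file. Of the 22927 tested, 17092 had a symbol of that table and 5835 did not. In the 3 comparisons, 4570 genes had several kept probes. Tested probe by probe, 0 of them had calls in both directions with Lin28b, 0 with let-7 and 208 between the tissues.

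Where a probe was not well above background on any array of a group, a change is given as a lower bound ("at least N-fold"), the brighter group's mean against, per array of the dimmer group, the higher of the probe's signal and the lowest signal well above background.

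The tools were R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8), and Python 3.11.15 for the plots. limma (lmFit, eBayes) fitted 1 mean per group over all 8 arrays, with contrasts for Lin28b in BM, for let-7 in FL, and between the 2 empty-vector groups. Adjusted p values are limma's with Benjamini-Hochberg adjustment over the 22927 tested, called below 0.05, and errors of fold changes are limma's standard errors. Between 2 and 2 arrays an exact permutation test cannot go below p = 0.333 (two-sided), so the calls rest on the spread that limma shares between genes (prior degrees of freedom 1.69). The number of arrays limits the precision.

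The design, the settings to be compared and the gene lists were fixed before the data were examined. The lists were let-7 targets, pro-B cell identity, later B cell stages, MHC class II, stem and multipotent progenitor genes, imprinted growth genes, cell cycle, IL-7 and STAT5 responses, p53 targets, interferon response, glycolysis and ribosome biogenesis. Markers of myeloid, erythroid, stromal, hepatocyte, dendritic, and T, NK and innate lymphoid cells were fixed with them. Lists were tested with camera (preset correlation 0.01), adjusted over the 18 lists of a comparison, and again with an estimated correlation and with fry. Genes named in the text are Lin28b, Lin28a, Arid3a, Igf2bp1, Igf2bp2, Igf2bp3, Hmga2 and Dntt; the 8 with the largest rise and the 8 with the largest fall among called genes with both arrays of 1 group beyond both of the other, well above background on both arrays of the higher group and with a gene symbol; up to 4 members per list by smallest adjusted p; and up to 10 genes called in both of 2 comparisons. Not every gene that the rule allows is named, and genes outside it are marked as chosen after their values were seen.

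The fit was tested on simulated data with known changes in 67, 67 and 66 of the 22927 genes, drawn with each tissue's own spread. Of the 67 genes changed by log2 1, it recovered 4.48% with Lin28b, 34.3% with let-7 and 11.9% between tissues. Of 67 changed by log2 2 it recovered 64.2%, 76.1% and 68.7%, and of 66 changed by log2 4 it recovered 90.9%, 93.9% and 90.9%. It also called 1, 110 and 28 unchanged genes. FL arrays spread more than BM arrays, so the shared spread is too small for FL and too large for BM.

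The 75th percentile of the signal was 1925 to 2234 on BM arrays and 271.5 to 487.9 on FL arrays. Between 64.4% and 68.6% of probes were well above background on the arrays of the first and second slide, against 56.5% and 57.0% on the third. Settings tried were normexp background correction (offset 50), quantile and median scaling, the authors' table, other filters on dim probes, every probe tested, only the 4 arrays of a comparison, eBayes with trend and robust, other thresholds (adjusted p below 0.1, or at least 2-fold), the replicate number as a block, the slide as a random block, and leaving out each array. The closing section gives their effect.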

Results

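Gene expression was measured in mouse pro-B cells, the early B cell stage, grown on OP9 stroma with IL-7 after transduction of Lin28b into adult bone marrow (BM) cells or of let-7b into fetal liver (FL) cells, each beside its empty vector. Lin28b is an RNA-binding protein that blocks the maturation of the let-7 microRNAs, so the series sets a gain of the let-7 inhibitor in adult cells beside a gain of let-7 in fetal cells. Each of the 4 groups held 2 arrays, from separate sorts. The 4 BM arrays lay on 1 slide with 1 scan. The FL arrays lay on the second and the third slide, each with 1 empty-vector and 1 let-7 array, so the replicate number and the slide were the same for FL. Correlations between arrays across genes were 0.991 to 0.994 within BM, 0.970 to 0.989 within FL and 0.910 to 0.943 between tissues. The median SD of a gene between 2 replicates was 0.08 for both BM groups, 0.29 for FL empty vector and 0.22 for FL let-7.

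Lin28b transduction of adult BM cells was tested first on the transgene. A Lin28b probe (mm9 chromosome 10, 45140412 to 45140471) lay at 0.21 ± 0.19 (SD, n = 2) with Lin28b and was not well above background with empty vector, at least 121-fold higher, with an adjusted p of 0.00315 (limma) where every probe was tested. A second Lin28b probe (chromosome 10, 45096468 to 45096527), the one that entered the gene-level test as the brighter over all arrays, differed by 0.64 ± 0.28 (adjusted p = 1; well above background on 1 of 2 control arrays). Which of the probes lies within the transgene is not analysed here. Mature let-7 was not measured here.

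With Lin28b, 0 of 22927 genes passed, and H19 had the smallest adjusted p. H19, an imprinted long noncoding RNA of fetal tissues, differed by 2.49 ± 0.16 (n = 2 per group, adjusted p = 0.179). Hmga2, a chromatin protein of fetal and stem cells, differed by 2.02 ± 0.26 (adjusted p = 0.709), and Igf2bp1, a fetal mRNA-binding protein, by 1.56 ± 0.20 (adjusted p = 0.709). Arid3a, a transcription factor of B lineage cells, differed by 1.07 ± 0.16, from 1.96 to 3.04 (adjusted p = 0.856). Dntt, which adds nucleotides at V(D)J joins and is low in fetal cells, differed by -0.83 ± 0.18 (adjusted p = 1). In each of these 5 genes both Lin28b arrays lay beyond both control arrays, which by chance holds for a share of 0.333 of genes. The other preselected genes had adjusted p = 1, namely Igf2bp2 (0.85 ± 0.51), Igf2bp3 (0.40 ± 0.23) and Lin28a (-0.41 ± 0.27).

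The smallest adjusted p of limma's test over all genes was 0.179. At an unadjusted p under 0.05, 447 genes were higher and 372 lower, 819 in all. Chance would give 1146 if the shared spread fitted these arrays. It is too large for BM (median SD 0.08, against 0.29 and 0.22 in FL), so chance would give fewer. How 819 compares with that number was not tested. H19 passed with quantile scaling (2.68 ± 0.13, adjusted p = 0.0235), and with eBayes with trend and robust (2.49 ± 0.14, adjusted p = 0.00837), where it was the single call. Its second probe differed by 0.15 ± 0.29, far below the first. Other settings called 0 to 4 genes higher and 0 or 1 lower.

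The let-7 targets rose as a list with Lin28b. Of 50 tested, 39 had a positive and 11 a negative fold change, with a median of 0.24 against -0.04 for all genes (camera adjusted p = 2.93e-14, adjusted p = 0.0319 with an estimated correlation). None passed over all genes, and 3 passed adjusted over the list alone, Hmga2, Igf2bp1 and Arid3a. Stromal markers lay higher as a list on the same arrays (median 0.88, 0 genes called, camera adjusted p = 0.379 with an estimated correlation), and whether RNA of the stroma adds to the rise of the targets was not tested. Pbx2, a homeobox cofactor, had the next smallest p (0.62 ± 0.14, adjusted p = 1).

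The interferon response list lay lower and the stromal marker list higher with Lin28b, both without a single gene called. All 24 interferon genes tested had negative fold changes, with a median of -0.87 (camera adjusted p = 3.89e-10, adjusted p = 0.757 with an estimated correlation). They included the transcription factor Irf9 (-0.55 ± 0.23) and Zbp1, a sensor of foreign nucleic acids (-0.86 ± 0.32). All 18 markers of stromal cells had positive fold changes, with a median of 0.88 (camera adjusted p = 9.59e-17, adjusted p = 0.379 with an estimated correlation), among them the adhesion receptor Vcam1 (1.19 ± 0.36), the collagen gene Col5a1 (1.11 ± 0.27) and Fstl1 (1.02 ± 0.24). The pro-B cell identity list lay lower (median -0.08, 20 of 26 negative, adjusted p = 0.0252, adjusted p = 0.757 with an estimated correlation), with Dntt, Lef1, a transcription factor of early lymphocytes (-0.38 ± 0.13), and the surrogate light chain Vpreb2 (-0.29 ± 0.12). Myeloid markers lay higher (median 0.14, mean 0.77, 13 of 21 positive, adjusted p = 0.0254, adjusted p = 0.757 with an estimated correlation). Among them S100a9, a granulocyte protein, was at least 25.7-fold higher (adjusted p = 1; -4.61 and 0.56 on the 2 Lin28b arrays, so mostly from 1 of them) and Tyrobp, an adaptor of myeloid receptors, differed by 0.69 ± 0.29. With the replicate number as a block, camera's adjusted p was 0.0597 for pro-B identity and 0.0583 for myeloid markers, and after quantile scaling 0.0593 for myeloid markers.

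The other 13 lists did not pass with Lin28b. The imprinted growth genes had a camera adjusted p of 0.0533, and 0.0439 after quantile scaling, with a median of -0.01 and a mean of 0.27. H19 was the single member to pass adjusted over the list alone, beside higher values of Mest (1.65 ± 0.63; well above background on 1 of 2 control arrays) and Meg3 (1.57 ± 0.78). Over the settings run, the value of Mest ranged from 0.59 to 2.44 and that of Meg3 from 1.07 to 2.06. Adjusted p values were 0.242 for later B cell stages (Ccr7, 0.59 ± 0.23, and Cd55, 0.58 ± 0.21), 0.747 for MHC class II (H2-Aa, -0.34 ± 0.15), 0.268 for stem and multipotent progenitor genes (Kit, -0.54 ± 0.20), 0.268 for the cell cycle, 0.747 for IL-7 and STAT5 responses, 0.253 for p53 targets, 0.201 for glycolysis (0.0115 after quantile scaling) and 0.253 for ribosome biogenesis. They were 0.796 for erythroid, 0.747 for hepatocyte, 0.351 for dendritic and 0.253 for T, NK and innate lymphoid markers. The hepatocyte list had a negative median (-0.16) and a positive mean (0.07), the later B cell list a median of -0.04 and a mean of 0.08, and the erythroid list a median of -0.12 and a mean of 0.06.

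**Figure D1:**
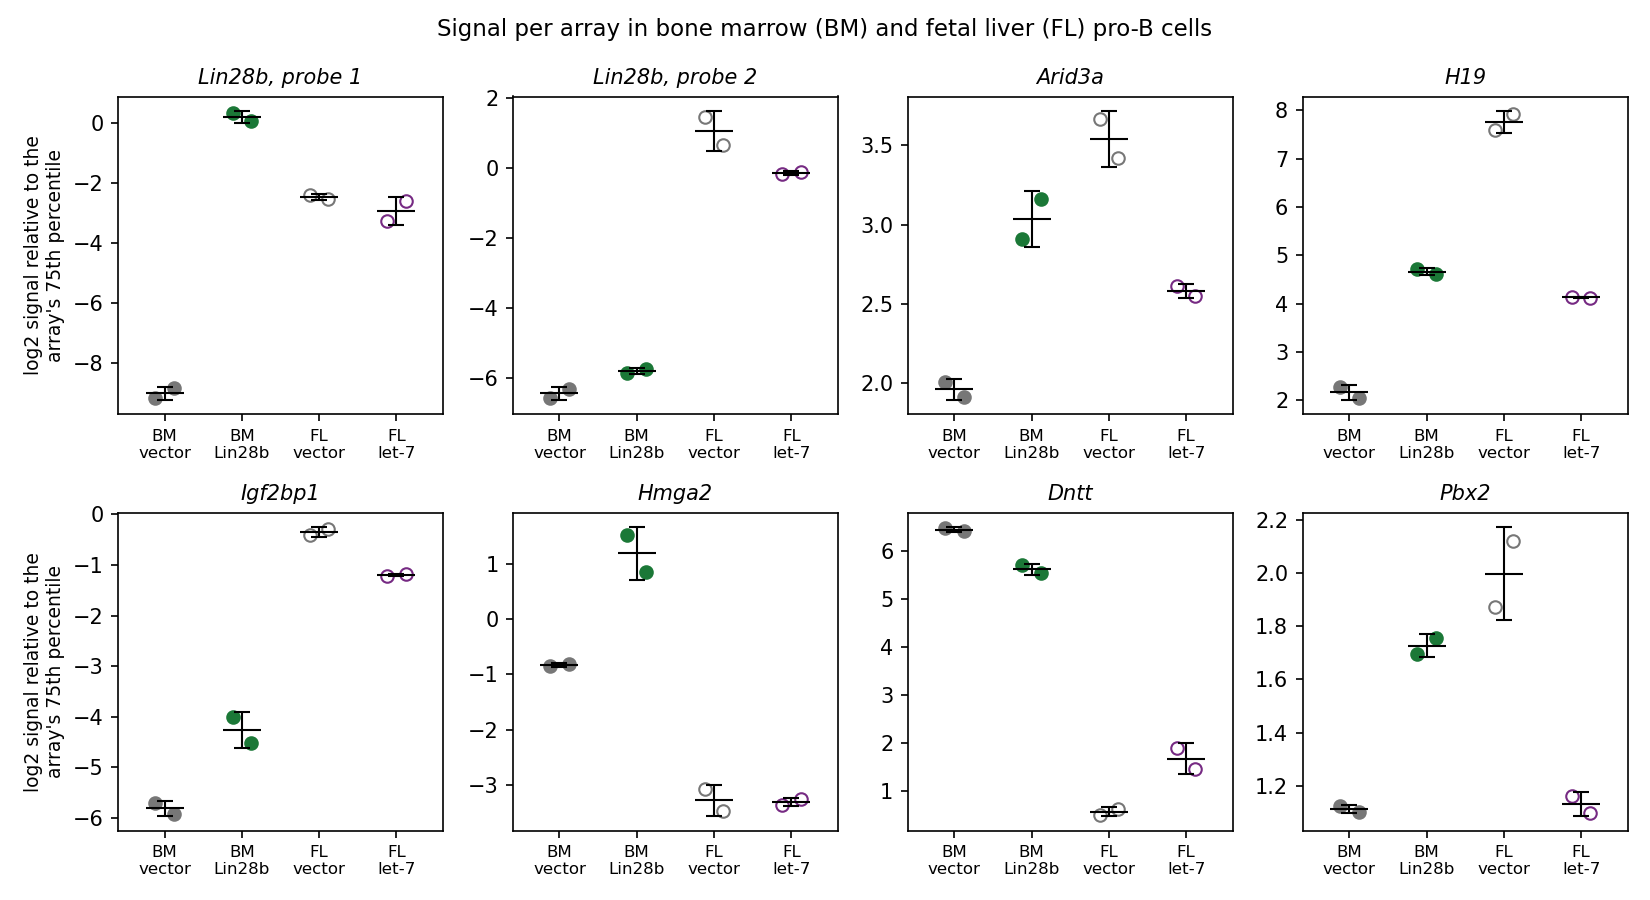
Each panel plots 1 probe's log2 signal relative to the array's 75th percentile (vertical axes differ between panels) on the 2 arrays of each group (points), with the mean and SD (bars). H19 lay at 2.17 in BM vector, 4.66 in BM Lin28b, 7.76 in FL vector and 4.13 in FL let-7 cells, and Arid3a, Igf2bp1 and Pbx2 had the same order of BM vector below BM Lin28b and FL let-7 below FL vector.

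In FL cells with let-7, limma called H19 and Hspa12b lower and 5 genes higher. These calls depended on the setting, with 0 genes called with normexp, in the authors' table, with no filter on dim probes, with only the 4 FL arrays or without any of 7 single arrays, and 305 higher and 217 lower without FL empty vector replicate 1. H19 fell by 3.63 ± 0.16 on the log2 scale (n = 2 per group, limma adjusted p = 0.0217), from 7.76 to 4.13. Its values were -3.47 on the second and -3.80 on the third slide, and its second probe differed by -0.44 ± 0.29. Hspa12b, a member of the HSP70 family, fell by 2.98 ± 0.17 (adjusted p = 0.036). Crhbp, which encodes the binding protein of corticotropin-releasing hormone, rose by 2.69 ± 0.17 (adjusted p = 0.0392), and the heavy-chain variable segment Ighv1-9 by 2.38 ± 0.17 (adjusted p = 0.04; well above background on 1 of 2 control arrays). The T cell receptor gamma segment Trgv2 was at least 1.92-fold higher (adjusted p = 0.0392). The other 2 genes lay outside the naming rule and were chosen after their values were seen: the uncharacterised AW112010 (2.06 ± 0.14) and ENSMUST00000113016 (2.07 ± 0.13), both with adjusted p = 0.0392. All 7 moved the same way on both slides.

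At an unadjusted p under 0.05, 1014 genes were higher and 1226 lower with let-7. Summed over 20 simulations of unchanged groups at each tissue's own spread, 59800 genes had such a p and 190 were called. Per simulation both numbers exceed those seen here, so neither the unadjusted count nor the 7 calls stand above them. The simulated arrays were independent, while FL arrays of 1 slide deviated together (correlation 0.517). With replicate and slide as a block, 0 genes passed in limma's test, 2787 had an unadjusted p under 0.05, and H19 had an adjusted p of 0.146. The block cannot alter fold changes in this balanced design, H19's error was 0.14 against 0.16 without it, and its larger p goes with fewer residual degrees of freedom. The block with trend and robust, chosen after the data were seen, called 76 genes higher and 57 lower, all 7 among them. At the spread of these arrays the simulation with known changes called 110 unchanged genes. With eBayes with trend and robust 58 genes were higher and 27 lower, and the simulation with known changes called 112 unchanged genes with that fit.

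Among preselected genes, Arid3a, Lin28b and Igf2bp1 had lower values and Dntt a higher one with let-7, and none passed. Arid3a differed by -0.96 ± 0.16 (adjusted p = 0.148, with -1.05 and -0.87 on the 2 slides), Lin28b by -1.20 ± 0.28 (0.27) and Igf2bp1 by -0.85 ± 0.20 (0.287). The other Lin28b probe, the one that rose with the transgene in BM, differed by -0.46 ± 0.27 with let-7. Dntt differed by 1.11 ± 0.18 (adjusted p = 0.152; 1.39 and 0.82 on the 2 slides). With trend and robust, Arid3a passed at an adjusted p of 0.0452 and Dntt did not (0.0523). Hmga2 (-0.03 ± 0.26), Igf2bp2 (-0.47 ± 0.51; well above background on 1 of 2 arrays in each group), Igf2bp3 (-0.21 ± 0.23) and Lin28a (-0.26 ± 0.27) lay within the spread of their replicates, and the sign of each of these 4 changed with the setting.

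The let-7 targets fell as a list with let-7. Of 50, 35 had a negative and 15 a positive fold change, with a median of -0.19 against -0.06 for all genes (camera adjusted p = 0.000714, adjusted p = 0.45 with an estimated correlation), and a median of -0.20 on each slide (adjusted p = 0.00248 with the block). None passed over all genes and 10 fell adjusted over the list alone, including Arid3a, Lin28b, Igf2bp1, Pbx2 (-0.87 ± 0.14), Dicer1, the nuclease that makes microRNAs (-0.88 ± 0.15), and Plagl2, a zinc finger protein (-0.87 ± 0.15). Between the 2 treatments, 29 of the 50 targets had a positive value with Lin28b and a negative one with let-7, and 5 the reverse. The Spearman correlation of the 2 fold changes across the 50 genes, which are not independent replicates, was -0.382.

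**Figure D2:**
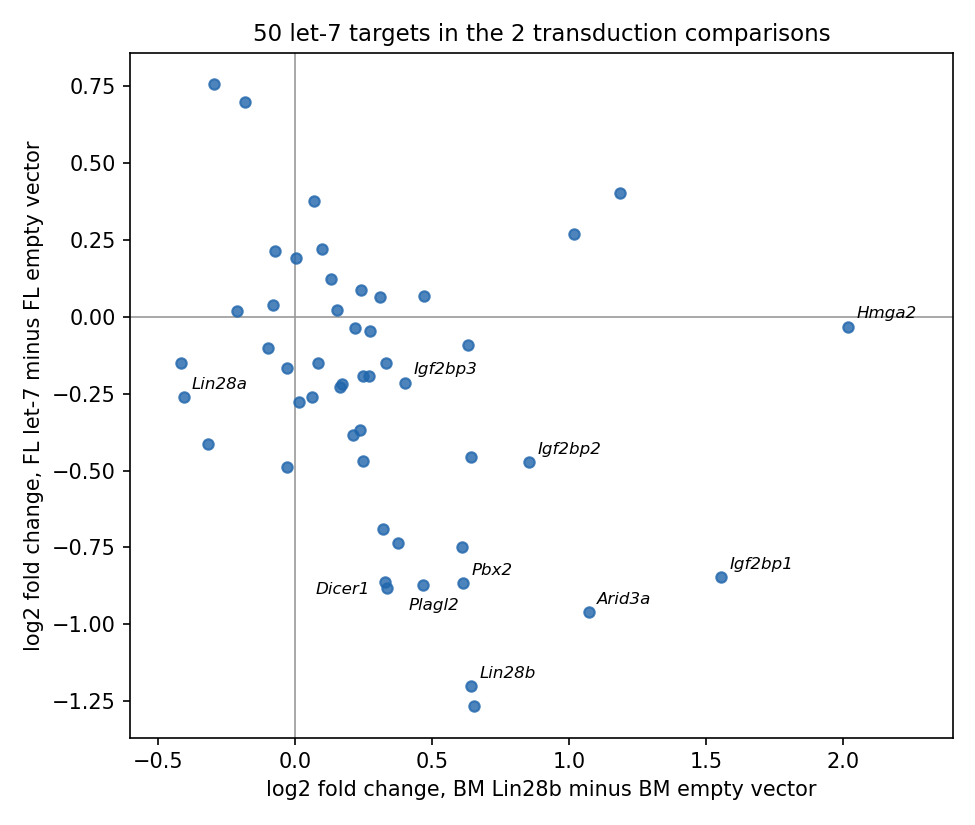
Each point is 1 of 50 let-7 targets, with its log2 fold change with Lin28b in BM cells (horizontal axis) and with let-7 in FL cells (vertical axis). The lower right quadrant, positive with Lin28b and negative with let-7, holds 29 genes, among them Arid3a and Igf2bp1, while Hmga2 at 2.02 with Lin28b lay at -0.03 with let-7.

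Interferon, stem and progenitor, MHC class II, pro-B identity and stromal lists lay higher with let-7, and glycolysis lower, with 0 genes of these lists called over all genes. None of the 6 held with an estimated correlation (adjusted p = 0.548 for each). The interferon list had a median of 1.55 with 23 of 24 positive (adjusted p = 1.27e-13), and 0.60 and 2.25 on the 2 slides, with Zbp1 at 1.53 ± 0.32 and Irf9 at 0.93 ± 0.23. The stem and progenitor list had a median of 0.54 with 14 of 19 positive (adjusted p = 0.000384; 0.23 and 0.44 on the slides), with the transcription regulator Lmo2 at 1.16 ± 0.20 and the stem cell factor receptor Kit at 0.82 ± 0.20. In the MHC class II list (median 0.30, 8 of 10 positive, adjusted p = 0.00799; 0.39 and 0.27 on the slides) H2-Eb1 differed by 1.20 ± 0.25 and H2-Aa was at least 1.21-fold higher (adjusted p = 0.0537), with a signal well above background on 1 let-7 array. Pro-B identity genes had a median of 0.06 with 17 of 26 positive (adjusted p = 0.00908; 0.12 and 0.03 on the slides; median 0.09 after quantile scaling), with Dntt, Spn, which encodes CD43 (0.73 ± 0.14), and the transcription factor Myb (0.51 ± 0.12). All 18 glycolysis genes had negative fold changes (median -0.28, adjusted p = 2.86e-05; -0.13 and -0.50 on the slides), with a smaller median of -0.14 after quantile scaling (adjusted p = 0.00851), including the glucose transporter Slc2a3 (-0.97 ± 0.13, adjusted p = 0.099) and Hk2, which phosphorylates glucose (-0.61 ± 0.14).

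Stromal markers had a median of 0.83 with let-7, with 14 of 18 positive (adjusted p = 2.94e-05). The shift was 1.19 on the second and 0.20 on the third slide, with Timp1, an inhibitor of matrix proteases, at 1.42 ± 0.33 and the matrix protein Sparc at 1.04 ± 0.31. In the later B cell list, which did not pass (adjusted p = 0.518, median -0.22, mean 0.08), 5 members rose and 2 fell adjusted over the list alone, including the chemokine receptor Cxcr5 (-1.21 ± 0.22). Adjusted p values of the remaining lists were 0.0629 for imprinted growth genes, 0.0693 for the cell cycle, 0.328 for IL-7 and STAT5 responses, 0.0625 for p53 targets, 0.73 for ribosome biogenesis, 0.827 for myeloid, 0.85 for erythroid, 0.722 for hepatocyte, 0.185 for T, NK and innate lymphoid and 0.909 for dendritic markers.

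With empty vector, FL and BM cells differed in 13657 of 22927 genes, 9194 higher and 4463 lower in FL. Tissue, vector, slide and scan differed together here, so they cannot be told apart. The median difference of all genes was 0.52, and 67.3% of calls were higher in FL. After quantile scaling the median difference was 0.04, with 5884 genes higher and 6085 lower (49.2% higher). Under both scalings 5840 genes were called higher and 4432 lower, while 101 called genes turned their sign. The named genes below kept their direction under quantile scaling and after subtraction of the 0.52.

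Of the preselected genes, 5 were higher and 2 lower in FL cells. Lin28b rose by 7.51 ± 0.28 (n = 2 per group, adjusted p = 0.000293; well above background on 1 of 2 BM arrays), and by its other probe at least 18.9-fold. Igf2bp1 rose by 5.46 ± 0.20 (0.000293), H19 by 5.59 ± 0.16 (0.000273), Igf2bp3, of the same mRNA-binding family, by 3.25 ± 0.23 (0.000581), Lin28a by 2.10 ± 0.27 (0.00185) and Arid3a by 1.58 ± 0.16 (0.00098). Dntt fell by 5.87 ± 0.18 (0.000289) and Hmga2 fell by 2.44 ± 0.26 (0.00112). Igf2bp2 differed by -0.41 ± 0.51 (0.509; well above background on 1 of 2 FL arrays), and by -1.22 after quantile scaling (0.0366).

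Among the largest rises in FL were Sntg2, a syntrophin (at least 258-fold), Sln, a regulator of the calcium pump (at least 51-fold), the lactate exporter Slc16a3 (7.47 ± 0.26, adjusted p = 0.000293), the peroxidase Pxdn (7.35 ± 0.24, 0.000293), Ccdc40 of motile cilia (6.75 ± 0.23, 0.000293) and the mitochondrial protein Mgarp (6.48 ± 0.19, 0.000273). Among the largest falls were Pgr, the progesterone receptor (at least 36.5-fold lower), and the homeobox gene Hoxb4 (at least 23.2-fold lower). They also included the engulfment receptor Megf10 (-7.09 ± 0.49, adjusted p = 0.000567, well above background on 1 of 2 FL arrays), the inflammatory caspase Casp4 (-6.04 ± 0.64, 0.00114), the adhesion protein Mpzl2 (-6.01 ± 0.23, 0.000326) and the chromatin remodeller Chd3 (-6.00 ± 0.14, 0.000273).

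Glycolysis genes were higher and ribosome biogenesis genes lower in FL cells. Of 18 glycolysis genes 17 rose and 0 fell, with a median of 2.25 (camera adjusted p = 9.64e-06, adjusted p = 0.706 with an estimated correlation) and 1.45 after quantile scaling, among them Aldoa (3.38 ± 0.19), Pkm (2.30 ± 0.13) and Pfkl (2.08 ± 0.12). Of 21 ribosome biogenesis genes 15 fell and 0 rose, with a median of -0.80 (adjusted p = 7e-07, adjusted p = 0.069 with an estimated correlation), among them the nucleolar proteins Gnl3 (-2.25 ± 0.17), Rrs1 (-1.54 ± 0.12) and Ebna1bp2 (-1.47 ± 0.12). MHC class II genes lay lower (5 of 10 fell and 1 rose, median -1.21, adjusted p = 0.0125), with H2-Eb1 at -2.93 ± 0.25, the invariant chain Cd74 at -2.25 ± 0.25 and H2-Aa at least 5.7-fold lower. Cell cycle genes lay lower (8 of 26 fell and 3 rose, median -0.30, adjusted p = 0.0444, and a median of -0.49 after quantile scaling), with Pcna (-0.93 ± 0.13) and Bub1 (-0.91 ± 0.15). The interferon list had a median of -0.53 with 3 higher and 4 lower (adjusted p = 0.0444, and 0.237 after quantile scaling), and stromal markers a median of -1.08 with 2 higher and 9 lower (adjusted p = 0.00831), with Timp1 at -3.32 ± 0.33. The interferon list's median level was 0.30 and -1.34 on the 2 FL control arrays, against 0.12 and 0.55 on the BM ones. Its lower value in FL thus came from 1 array. With an estimated correlation, adjusted p was 0.706 for MHC class II, cell cycle and stromal lists and 0.725 for interferon.

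Imprinted growth genes did not pass camera (adjusted p = 0.0693, and 0.0421 after quantile scaling), though 9 of 13 rose and 1 fell, with Grb10 at 4.42 ± 0.25 and Cdkn1c, an inhibitor of the cell cycle, at 2.48 ± 0.24. The let-7 targets were split, with 15 higher and 16 lower of 50 (median 0.03, mean 0.21, camera adjusted p = 0.231 in the downward direction against the other genes). In the pro-B identity list 12 of 26 rose and 5 fell (adjusted p = 0.791), with the recombinase Rag1, whose gene these mice lack (2.72 ± 0.25; its probe need not lie in the deleted part, so it does not check the genotype), and the receptor subunit Cd79a (1.94 ± 0.18). Other adjusted p values were 0.896 for later B cell stages, 0.536 for stem and progenitor genes, 0.231 for IL-7 and STAT5 responses, where the survival kinase Pim2 rose by 2.60 ± 0.20 with 9 other members, and 0.108 for p53 targets. Markers of other cells with higher values in FL were Csf1r of macrophages (4.05 ± 0.41), Fga of hepatocytes (3.86 ± 0.26) and Cd3e of T cells (3.56 ± 0.35), while Lyz1 of myeloid cells fell by 4.76 ± 0.23 (adjusted p = 0.000371, well above background on 1 of 2 FL arrays). Of 21 myeloid markers 7 were higher and 3 lower. As lists, myeloid (adjusted p = 0.574), hepatocyte (0.536), T, NK and innate lymphoid (0.231), dendritic (0.231) and erythroid markers (0.246) did not pass.

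**Figure D3:**
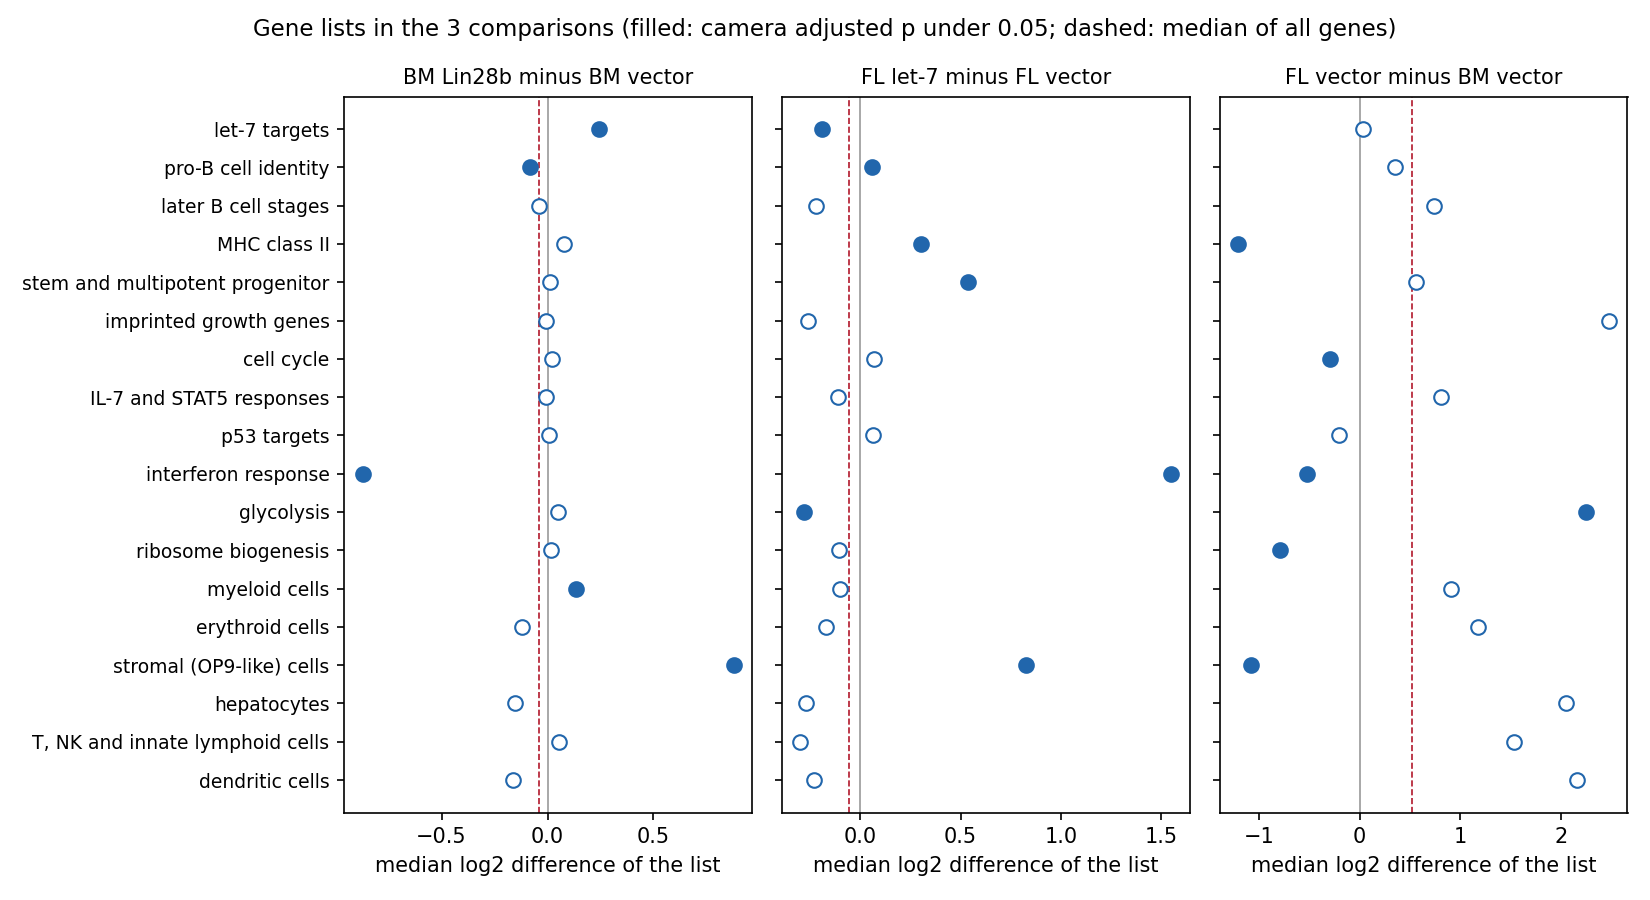
Points give the median log2 difference of each of 18 gene lists in the 3 comparisons (horizontal scales differ), filled where camera's adjusted p with the preset correlation was under 0.05, and dashed lines give the median of all genes. The interferon list lay at -0.87 with Lin28b and 1.55 with let-7, and the stromal list at 0.88 and 0.83.

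The 7 genes called with let-7 had the opposite direction between FL and BM, with all 7 called there, 5 higher with let-7 and lower in FL and 2 the reverse, where independent lists would share 0.973 and 0.802. In groups without any difference, the shared FL control arrays alone give such signs. In 20 simulations of unchanged groups, a share of 0.958 of the genes called with let-7 had the opposite sign between FL and BM, while 10 simulations gave on average 0.1 genes called in both. These simulations hold no difference between tissues. The 7 genes differed between FL and BM by absolute values of 1.44 to 5.59, with errors of 0.13 to 0.17. The simulations therefore cannot tell how far the shared arrays set these signs. H19, for example, differed by 5.59 between FL and BM and by -3.63 with let-7. Across 22927 genes the let-7 and FL fold changes correlated at -0.41, against -0.629 for simulated unchanged groups that share the FL control arrays, and the covariance was -0.288 against a simulated -0.113. Without a simulated tissue difference, -0.629 is not a reference for the correlation. The simulated arrays were also independent, while FL arrays of 1 slide deviated together (correlation 0.517). The simulated covariance is thus only a rough reference. With each control array used in 1 comparison the correlation was -0.172 or -0.0356 and the covariance -0.146 or -0.04, depending on which. In the Lin28b comparison, which shares no array, 6 of the 7 had the opposite sign to let-7, H19 at 2.49 among them, and as a signed set they moved against let-7's direction (limma's fry, adjusted p = 0.00196). Of these 6, H19 was by far the largest with Lin28b, and the others lay between 0.15 and 0.85 in absolute value. The 85 genes called with trend and robust had the opposite sign to let-7 in 73 cases with Lin28b (limma's fry, adjusted p = 0.00672). Both comparisons take a gene's spread from all 8 arrays. Genes called with let-7 partly for a small spread keep that spread with Lin28b, so both fry p values can be too small.

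Over all genes, the responses to Lin28b and let-7 were nearly uncorrelated (-0.0199, against -5.4e-06 in simulated unchanged groups), and 0 genes passed limma's test in both. The Lin28b and FL fold changes correlated at -0.0662, against 0.326 simulated, with a covariance of -0.0383 against 0.0301, and at -0.114 or -0.15 with each control array used in 1 comparison. The simulated groups held no tissue difference, so 0.326 is not a reference for this correlation, while the covariances can be compared. With 0 genes called with Lin28b, 0 were shared with the FL difference.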

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

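Chosen after the data were seen were the fits with the replicate block plus trend and robust, without the third slide, and with 1 array weight per tissue, the list tests after quantile scaling, the 20 simulations of signs, and the trend and third-slide values of named genes. With 2 arrays per group the counts of calls depend on the setting in both transduction comparisons, while the FL to BM difference kept many calls in both directions under each setting run. Causes were not tested, except where fewer arrays or genes explain a count by construction. The dim FL arrays, above all those of the third slide, limit what can be seen near background. The authors' table was not run for the FL to BM difference, since its tissues were normalized separately. Without an array, the lone array of its group is assumed to vary like the others.

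With Lin28b, limma called 0 genes higher and 0 lower, and 2 and 0 with quantile scaling (H19 and Olfr1082), 2 and 1 in the authors' table (Olfr1082, Tigd4 and, lower, 2310065F04Rik), 3 and 1 with the slide as a random block (these 3 with H19), 0 and 1 with only the 4 arrays of the comparison (2310065F04Rik), and 1 and 0 with trend and robust (H19). Except for H19, these names were chosen after their values were seen. Counts were 1 and 0 with probes well above background on all 8 arrays, 1 and 0 with every probe tested (Lin28b), 1 and 1 with the replicate block with trend and robust, 0 and 1 without the third slide, and 4 and 1 with array weights. They were 0 and 0 with the other settings and without any 1 array (range 0 to 0).

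With let-7, the 5 higher and 2 lower genes became 57 and 29 with quantile scaling, 20 and 4 with the median shift, 52 and 34 with probes well above background on all arrays, 58 and 27 with trend and robust, 49 and 25 at an adjusted p under 0.1, 132 and 106 with the slide as a random block and 76 and 57 with the replicate block with trend and robust. They became 0 and 0 with normexp, in the authors' table, with no filter, with only 4 arrays, without the third slide and with array weights. Without FL empty vector replicate 1 the counts were 305 and 217, and without any other 1 array 0 and 0.

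With the replicate number as a block, limma called 0 genes with Lin28b (1390 at an unadjusted p under 0.05), 0 with let-7, where it is also the slide, and 15332 between FL and BM. It changed the list calls of pro-B identity and myeloid markers with Lin28b and no other camera call. The labels divide the wells of a plate between virus and empty vector but call the samples individual sorts, and do not state that samples of 1 number share a plate. Deviations of arrays with 1 number correlated at -0.0553 in BM and 0.517 in FL.

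Between FL and BM, the 9194 higher and 4463 lower genes became 5884 and 6085 with quantile scaling, 4348 and 8269 with the median shift (median difference -0.30), 8787 and 1647 with normexp, 14771 and 4165 with no filter and 7235 and 2610 at 2-fold. Under all 3 scalings 3591 were called higher and 4432 lower. Without 1 array each they ranged from 6331 to 9673 and from 2719 to 4587, with the fewest lower without BM empty vector replicate 1 (2719) or 2 (2761).

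Genes called in opposite directions with Lin28b and let-7 numbered 0, and 1 with quantile scaling, probes measured on all arrays, trend and robust, the random slide block, or the replicate block with trend and robust (0 to 0 without 1 array). Their correlation of -0.0199 was -0.101 with normexp, -0.0982 in the authors' table, -0.0935 with probes measured on all arrays and 8.23e-05 with no filter, and ranged from -0.0559 to 0.0352 without 1 array (0.0156 without BM Lin28b replicate 2, 0.0242 without FL let-7 replicate 1). Genes shared by Lin28b and the FL difference in the same direction numbered 0, and 1 with quantile scaling, probes measured on all arrays, every probe, trend and robust or the replicate block with trend and robust, and 3 with the random slide block or array weights (0 to 0 without 1 array). Their correlation of -0.0662 was -0.131 with normexp, -0.129 with probes measured on all arrays, -0.114 and -0.15 with split controls, and -0.0923 to 0.0376 without 1 array (0.0376 without BM empty vector replicate 2).

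Genes opposite with let-7 and in the FL difference numbered 7, and 73 with quantile scaling, 24 with the median shift, 76 with probes measured on all arrays, 77 with trend and robust, 70 at an adjusted p under 0.1, 171 with the random slide block and 116 with the replicate block with trend and robust. There were 0 with normexp, no filter, 4 arrays, the replicate block, without the third slide or with array weights, and 437 without FL empty vector replicate 1 against 0 without any other 1 array. Their correlation of -0.41 was 0.278 with normexp, -0.247 without the third slide, -0.172 and -0.0356 with split controls, and -0.494 to -0.176 without 1 array.

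Of the 18 lists, 5 passed with Lin28b, 7 with let-7 and 6 between tissues. These became 1, 0 and 0 with an estimated correlation, 1, 0 and 12 with fry, 3, 7 and 6 with the replicate block and 6, 7 and 6 after quantile scaling. A larger p with an estimated correlation need not mean that a list's members are correlated. For ribosome biogenesis the estimate was -0.0129, below the preset 0.01. Camera's unadjusted p between tissues still went from 3.89e-08 to 0.00383, so the correlation alone does not set the change. With quantile scaling, glycolysis (adjusted p = 0.0115) and imprinted growth genes (0.0439) passed with Lin28b and myeloid markers did not (0.0593), while between tissues imprinted growth genes passed (0.0421) and interferon genes did not (0.237). Fry, which does not compare a list with other genes, put the let-7 targets between FL and BM upward (adjusted p = 0.00732), against camera's downward value (0.231).

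Genes named by the rule fixed in advance kept their sign in the settings run but for these. The sign of genes chosen after their values were seen was not followed across settings. With let-7, Lin28a was 0.088 with normexp, -0.655 without FL let-7 replicate 1, 0.13 without FL let-7 replicate 2 and 0.22 without the third slide. Igf2bp2 was 0.68 with normexp, 0.07 without FL empty vector replicate 1, -1.045 without FL let-7 replicate 1 and 0.10 without FL let-7 replicate 2. Igf2bp3 was 0.064 without FL empty vector replicate 1 and -0.4915 without replicate 2. Hmga2 was 0.59 with normexp, 0.030 in the authors' table, 0.17 without FL empty vector replicate 1, -0.233 without FL empty vector replicate 2 and 0.02 without FL let-7 replicate 1. Igf2bp2 between FL and BM was 1.02 with normexp, -0.953 without FL empty vector replicate 1 and 0.13 without FL empty vector replicate 2 or the third slide.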

Other observations

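The tests in this part were chosen after the results were seen. Exceptions are the correlation over all genes, limma's adjusted tests of single genes, and camera with an estimated correlation on the lists fixed in advance. Genes at a small unadjusted p with both treatments had opposite signs more often than equal ones. At an unadjusted p under 0.05 in both limma comparisons, which share no array, 260 genes overlapped, 168 in opposite and 92 in the same direction, where 20 simulations of unchanged groups, fitted alike so that both comparisons share a gene's spread, gave on average 28.9 and 27.4 (highest 37 and 37). Both counts exceed the simulated ones, and the correlation over all genes was only -0.0199. Of the 168, 79 were higher with Lin28b and lower with let-7, and 89 the reverse. The opposite genes outnumbered the others under each setting tried, by 190 to 103 with quantile scaling, 17 to 13 with normexp, 137 to 91 with the median shift, 190 to 85 with trend and robust, 256 to 137 with the replicate block, 219 to 69 with only the 4 arrays of each comparison, 299 to 77 in the authors' table and 671 to 373 without the third slide. Genes are not independent, and limma's adjusted test called 0 of them in both comparisons, while H19 was called in both with quantile scaling and with trend and robust. The named members below were chosen after their values were seen. Arid3a and H19 were among them, as were Tnni2, a troponin (1.07 ± 0.14 with Lin28b, -1.77 ± 0.14 with let-7 and 1.78 between FL and BM), the cyclooxygenase Ptgs1 (1.29 ± 0.28, -1.58 ± 0.28 and 1.25), the receptor Notch3 (1.01 ± 0.35, -1.75 ± 0.35 and 4.44) and Acsbg1, which activates fatty acids (1.10 ± 0.17, -1.17 ± 0.17 and 4.05). In the other direction were Vipr1, a receptor of vasoactive intestinal peptide (-1.45 ± 0.35, 4.18 ± 0.35 and -2.71; well above background on 1 of 2 FL control arrays), and the serpin Serpina3f (-1.24 ± 0.28, 2.21 ± 0.28 and -1.15). Errors are limma's, n = 2 per group.

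Part of the probes for heavy-chain variable (V) segments lay higher with let-7. The region between the probes of Adam6a and Zfp386 (mm9 chromosome 12, 114784624 to 117298953) held 90 tested genes, 39 on the far side of its midpoint and 51 on the near side. On the far side 31 of 39 were positive with let-7, with a median of 1.17 (camera p = 4.56e-22, p = 0.0177 with an estimated correlation, p = 1.42e-16 with the slide as a block). Its medians on the 2 slides were 1.25 and 0.72. The near side had 24 positive and 27 negative, with a median of -0.07 that was 0.09 after quantile scaling. Its medians on the 2 slides were 0.18 and -0.17. Its camera p was 0.00456 (p = 0.183 with an estimated correlation). Camera compares the members' mean statistic, not their median, with that of other genes. This p beside a negative median thus does not mean a fall, and its direction is not given here. Near-side values ran from -2.70 to 2.42. With Lin28b the far side had a median of -0.39, with 36 of 39 negative (p = 1.56e-11, p = 0.0534 with an estimated correlation), and the near side 0.02. Between FL and BM, 67 of 90 genes were called lower in FL and 4 higher. Since 25 of 39 far and 10 of 51 near probes were well above background on both FL control arrays, the size of this difference is not given. Among genes well above background on at least 2 of the 4 FL arrays, the near side had a median of 0.62 with let-7, with 10 of 17 positive. The far side had 1.21, with 27 of 32 positive. The contrast between the sides was thus smaller among measured genes, and the near-side median of -0.07 rests largely on dim probes. Of single genes, 1 of 90 was called with let-7. It was Ighv1-9, which lies on the near side, and 0 far-side genes were called.

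Over all 90 probes, fold change and position had Spearman correlations of 0.467 with let-7 and -0.611 with Lin28b, which restates the split into sides. A permutation test of position (10000 permutations) gave p = 1e-04 for each of these 2. Between FL and BM the correlation was -0.059 (permutation test, p = 0.584). Among the 49 probes well above background on 2 or more FL arrays, the correlation with let-7 was 0.285 (permutation test, p = 0.049). Position was not tested apart from the split into sides, and 23 near-side probes were below background on all 4 FL arrays. A general rise of probes of the same mean signal is argued against, since the medians of random lists matched on it had an upper bound of 0.0825. These lists were not matched on signal in FL alone. Of the 39 far-side probes, 38 were well above background on both BM control arrays, against 25 on both FL ones. A general rise of probes dim in FL thus stays open. V segments resemble each other, so probes may share targets, which was not tested. Per the labels these mice lack Rag1, which is needed to join V segments, but what the probes detect was not tested, nor whether let-7 acts on transcription of the segments.

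Markers of stromal cells lay higher as a list with Lin28b, with 0 genes called. The markers had been fixed in advance, and 18 of 18 were positive, among them the most abundant, as Fn1 went from 3.41 to 4.28, Col1a2 from 1.91 to 2.99 and Sparc from 1.79 to 2.67. More RNA of the OP9 stroma in the Lin28b samples stays open, since the 18 positive markers are the pattern itself and no separate test of it was made. The sort for GFP should remove cells without vector, and all 18 were above background in the BM controls too. A lower share of pro-B cells with all other types raised alike is argued against only weakly, since 54 markers of myeloid, erythroid, dendritic, T, NK and innate lymphoid cells had a median of 0.00903 (bootstrap upper bound 0.14) against 0.88. These lists were dim, with median levels of -5.01 to -3.69 on the BM control arrays, against -0.47 and -0.36 for the stromal list. The same list also lay higher with let-7 in FL cells (median 0.83, 14 of 18 positive, 1.19 and 0.20 on the 2 slides), so a rise was not particular to Lin28b. An effect of Lin28b on expression of these genes within the sorted cells stays open and was not tested.

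Interferon response genes lay lower with Lin28b and higher with let-7. Slide and scan are argued against, since all 4 BM arrays shared 1 slide and let-7 exceeded its control within both FL slides, with a smaller median of 0.6. Scaling is argued against by medians of -0.846 and 1.56 after quantile scaling. Differences between cultures of 1 group could account for the let-7 part, since the 2 FL control arrays differed by a median of 1.67, more than the 1.55 between treatments. These 2 arrays also lay on different slides, and the 2 let-7 arrays on the same slides differed by a median of only -0.0576. In BM the largest difference between replicates was 0.395 against -0.872 between treatments, and the list did not pass there with an estimated correlation (camera adjusted p = 0.757), so differences between cultures stay open, as does an effect of Lin28b or let-7.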
